A study of Homo sapiens with 63 samples.

How the data were processed

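RNA of GIST-T1 cells and xenografts was measured in 63 libraries from 17 groups: 15 libraries of guide-expressing cells (3 per guide), 20 of drug-treated cultures and 28 of xenografts (4 per group). The source label names GIST-T1 for every sample, while the cell line tag counts up from GIST-T1 to GIST-T63, which was taken as a spreadsheet fill. Per the labels' protocols, polyadenylated RNA was purified with an RNeasy Plus kit, made into libraries with a NEBNext Ultra II DNA kit and sequenced as paired-end reads of 150 bp on a NovaSeq instrument. The authors deposited FPKM (fragments per kilobase of transcript per 1e6 mapped fragments) per gene in 3 tables, one for each kind of sample. STAR, Cufflinks and the hg19 genome are named without versions per the submitters' processing notes, and neither strand, nor filters, nor any further scaling between libraries is stated. Each table held 23610 entries. In each, 28 entries (0.119%) had a spreadsheet date in place of a gene symbol and were left out, since the gene could not be read back with certainty. All 63 value columns were matched to a sample, with 0 left unmatched, and no pair of libraries was identical (highest correlation between libraries 0.99339, 0.99106 and 0.99016 in the guide, drug and xenograft tables).

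The deposited FPKM values were transformed as log2(FPKM + 1), with a pseudocount of 1. Genes with at least 1 FPKM in at least as many libraries as the smallest group were tested, which left 11728 genes for the guides, 12369 for the drugs and 12453 for the xenografts. Each table was fitted on its own with all its groups in one model by limma 3.58.1 in R 4.3.3 (eBayes with trend), and contrasts were tested with two-sided p-values adjusted by Benjamini and Hochberg at 0.05. Contrasts compared each guide with sgLuc, each drug with DMSO and each xenograft group with vehicle, then groups with each other, time points within a drug, and the interaction of VTP50469 with WM1119 or imatinib. In all, 30 comparisons were made. Replicate numbers did not pair libraries: within a comparison, deviations of libraries of the same number correlated across genes between -0.31 and 0.23, so no block was fitted in the main model.

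Gene lists, 36 in number and covering chromatin complexes, lineage, signalling, cell cycle, metabolism, stress, immune genes, markers of other cells and RNA quality, were written before the data were examined, as were the samples' groups, the tests, the alternatives and the rule for naming genes. A list with at least 3 tested members was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Counts of members are given over all genes tested and adjusted over the list alone. A list without members in the tables, such as mitochondrially encoded messages, was not tested. Named genes are the targeted genes with KAT6B, DOT1L and KIT in any comparison. In comparisons with a control, they are also the 12 largest rises and 12 largest falls among genes past the threshold, with a mean of at least 5 FPKM in a group and no overlap between the libraries of the groups. In other comparisons the 5 largest in each direction were taken, and for a list described, up to 4 members with the largest change. Genes listed at 0 in a library are mostly left out of the text, and some other genes that met these rules are not named. Levels of DKK4, EGR1, FOS, DUSP6, KIT and similar genes in further groups were chosen after their values were seen.

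Correlations of fold changes were computed across genes. Where comparisons share a control, 100 simulations of unchanged groups against that control gave the correlation and covariance that sharing alone produces, and with 4 controls the correlation was also averaged over 6 splits of the control libraries. Symbols were matched to GENCODE 29 transcripts of GRCh38 for GC content and length only (92.8, 92.2 and 92.5% of tested genes), and no coordinates are given because that build differs from hg19. The GC and length trend was fitted within each library on splines with 6 and 4 degrees of freedom (splines 4.3.3). FPKM holds no read counts, so relative depth was read from ratios of FPKM below 0.1 between a library and a reference library, which cluster at 1 value when both come from 1 fragment; ratios within 0.5% were counted together. The peak was clear in all libraries but combination 10-day replicate 2. No counting error can be given.

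The code was tested on simulated data built on the spread of the real libraries. For sgKAT6A against sgLuc (11728 genes), 52.2, 94 and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 2.98% false calls. For VTP50469 against DMSO (12369 genes) the shares were 40.3, 95.5 and 100%, with 7.1% false calls, and for VTP50469 at 10 days against vehicle (12453 genes) 43.3, 91 and 97%, with 5.52%. In each, camera called 2 of 2 shifted lists and 1, 0 and 0 others. A simulated GC trend led to calls for 5101, 5116 and 4307 unchanged genes, which removal of the trend took to 4, 13 and 7. The simulated trend was linear in the same GC values that the removal uses. It checks the code and not the removal of other bias.

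Alternatives tried were a pseudocount of 0.1, no filter beyond a value above 0, a filter on a mean of at least 5 FPKM, median centring, quantile normalization, a replicate block, library weights, a fit on the compared groups only, each library left out in turn, and the form of the xenograft sample names as a term. Chosen after seeing the data were leaving out the libraries that stood apart, using libraries of one name form only, and removing the GC and length trend. The libraries left out in turn were those of the groups in each comparison. Numbers of genes under other splits of the same libraries were counted over all splits, or over 100 drawn ones. Figures were drawn with matplotlib 3.10.9 and arrays handled with numpy 2.4.6 in Python 3.11.15.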

Results

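Polyadenylated RNA from GIST-T1, a human gastrointestinal stromal tumor cell line that depends on the receptor tyrosine kinase KIT, was measured by RNA sequencing in 63 libraries. In 15 of them cells carried guide RNAs against luciferase (sgLuc, the control), MEN1, KMT2A, KAT6A or BRPF1, with 3 libraries per guide. The descriptions of 14 of these samples mention VTP50469 or WM1119, and the cells were taken as untreated from their titles and treatment labels. In 20 libraries cells were cultured with DMSO, the menin inhibitor VTP50469, the KAT6A and KAT6B inhibitor WM1119, both compounds, or the DOT1L inhibitor EPZ5676, with 4 per group. The other 28 came from GIST-T1 xenografts given vehicle, or imatinib (a KIT inhibitor), VTP50469 or their combination for 5 or 10 days, with 4 per group. The labels give 24 h and 5 days as drug exposures in culture but not which library had which. They do not say whether replicates are separate cultures or animals, so each p-value measures only the spread between these samples. FPKM gives no read counts, so depth was known only relative to one control library of each table: it lay between 0.642 and 0.943 for the guides, 0.79 and 1.3 for the drug cultures and 0.647 and 1.28 for the xenografts. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given ± SE.

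MEN1, the gene for menin, fell in all 3 sgMEN1 libraries, which held 11.3, 12.3 and 10.9 FPKM against 36.7, 35.6 and 36.0 in sgLuc (log2 fold change -1.57 ± 0.08, limma adjusted p = 6.86e-09, n = 3 per group). BRPF1, a scaffold of the KAT6A acetyltransferase complex, stood at 4.08, 3.56 and 4.62 FPKM in sgBRPF1 against 8.21, 8.05 and 7.30 (-0.80 ± 0.14, limma adjusted p = 0.0361). That call was lost with median centring (adjusted p = 0.0628), with a replicate block (0.0819), on the compared groups only (0.0511) and without the expression filter (0.0564). KMT2A, listed as MLL, did not pass in sgKMT2A: its libraries held 2.47, 4.61 and 3.40 FPKM and overlapped the 5.2, 4.69 and 3.74 of sgLuc (-0.32 ± 0.18, limma adjusted p = 0.291). KAT6A did not pass in sgKAT6A either, with 28, 28 and 33.7 FPKM against 39.4, 36.9 and 33.8 (-0.29 ± 0.13, adjusted p = 0.473). A guide can disrupt a protein without lowering its messenger RNA, so these levels check the labels of sgMEN1 and sgBRPF1 only.

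**Figure D1:**
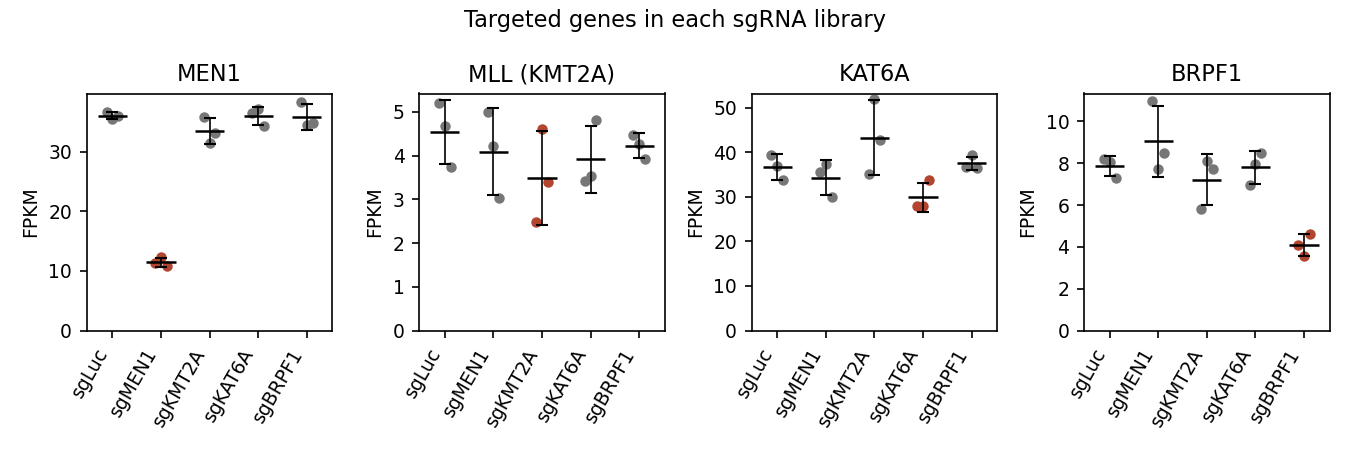
FPKM of MEN1, MLL (KMT2A), KAT6A and BRPF1 in each of the 15 guide libraries, as points, with bars for the mean of 3 and error bars for the SD; the group whose guide targets the gene is in red. MEN1 lay between 10.9 and 12.3 FPKM in sgMEN1 and between 35.6 and 36.7 in sgLuc, while MLL overlapped its controls.

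The sgMEN1 comparison asks what transcription in this tumor line needs menin, the scaffold that tethers the KMT2A and KMT2B methyltransferases to promoters. KIT itself, the driver of this tumor, fell from 209 ± 11 to 93.7 ± 21 FPKM (SD, n = 3; log2 fold change -1.17 ± 0.13, limma adjusted p = 5.14e-06). DUSP6, a phosphatase induced by ERK signalling, fell from 181 ± 3.6 to 54 ± 5.7 FPKM, and the homeobox gene HOXD4 from 14.3 ± 2.6 to 2.08 ± 0.81. Rises were largest for IGFBP3, which binds insulin-like growth factors (2.40 ± 0.11), the membrane protein gene VSTM2A (2.23 ± 0.17) and TAGLN, an actin-binding smooth-muscle gene (1.90 ± 0.20). The immune-ligand gene SECTM1 (1.87 ± 0.17), the stress gene NDRG1 (1.78 ± 0.13), the matrix gene TNC (1.60 ± 0.12), the sulfatase gene SULF2 (1.55 ± 0.13), EHD2 of caveolae (1.53 ± 0.09), the ion-channel gene ZACN (1.5 ± 0.17), the protease gene ADAMTS8 (1.48 ± 0.11) and RARRES3 (1.46 ± 0.18) rose too. DKK4, a secreted WNT antagonist, went from 92.7 ± 2.8 to 243 ± 37 FPKM.

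Falls after sgMEN1 were larger than rises, and several of the largest varied widely between its libraries, such as EIF3E with 46.7 ± 76.3 FPKM against 307 ± 6.9 in sgLuc. SRP9, a subunit of the signal recognition particle, fell by 4.16 ± 0.16, and the chromatin genes HMGN5 and CBX3 by 4.08 ± 0.33 and 3.96 ± 0.47. EIF3E of translation initiation (-4.69 ± 0.94), the respiratory subunit NDUFA5 (-3.99 ± 0.51), the actin regulator TWF1 (-3.76 ± 0.51), the polymerase subunit POLR2K (-3.72 ± 0.60), HSPB11 (-3.72 ± 0.68), SYNC (-3.71 ± 0.54) and the mitotic kinase TTK (-3.71 ± 0.52) followed. The histone H3.3 pseudogene H3F3AP4 had the largest value (-5.30 ± 0.77) and shares sequence with its parent genes, so its reads are uncertain. Of 11728 genes tested, 7128 passed in limma (2447 higher, 4681 lower, 60.8%), and 1942 of the falls and 126 of the rises exceeded 1 on the log2 scale. The median of all genes was -0.14, and median centring gave 5075 genes higher and 3045 lower, so the split by direction depends on scaling.

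Across genes, which are not independent replicates, the sgMEN1 fold changes followed transcript GC content with Spearman's rho of 0.734, against -0.0939 for sgKMT2A, -0.115 for sgKAT6A and -0.044 for sgBRPF1. The median log2 fold change ran from -1.36 in the group of genes with the lowest GC content of 10 equal groups (37.2%) to 0.305 in that with the highest (64.4%). Removing the GC and length trend, a setting chosen after seeing the data, left 3565 of 6691 called genes called in the same direction and turned 498 to a call in the opposite one. Genes that kept their calls included KIT -0.81 ± 0.08, HOXD4 -2.75 ± 0.25, IGFBP3 2.22, DKK4 1.13, DUSP6 -1.81 and SRP9 -2.90. Library sgMEN1 replicate 2 stood apart from its group on the first principal component (36.9 against 81.9 and 84.2).

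**Figure D2:**
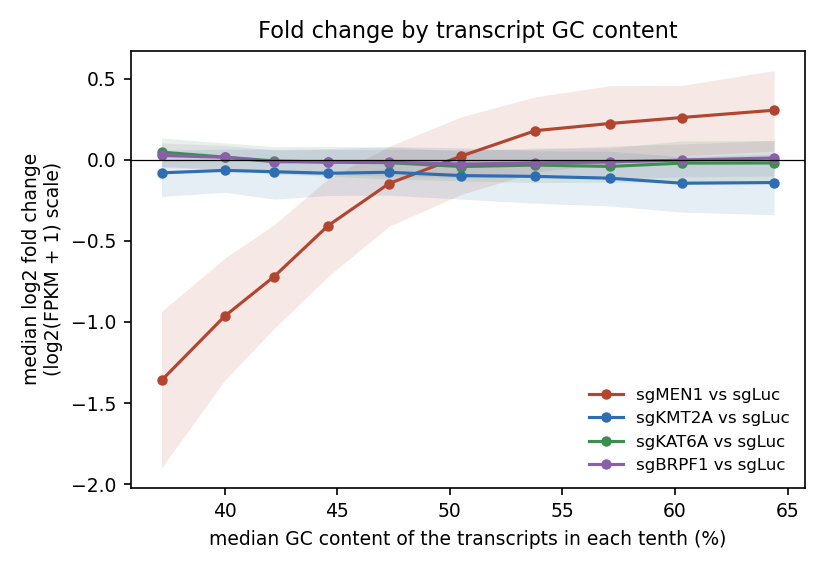
Median log2 fold change against sgLuc (vertical axis; band, quartiles) by 10 equal groups of genes ranked on GC content of the reference transcript (horizontal axis, percent) for the 4 guides, each with 3 libraries against 3. The sgMEN1 line climbs from -1.36 to 0.305.

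Among fixed lists, extracellular matrix genes were the clearest after sgMEN1: 12 of 17 were higher and 1 lower, the same counts adjusted over the list alone, with THBS1 at 1.28 and FN1 at 1.03 (camera adjusted p = 0.000613, but 0.458 with an estimated correlation and 0.0654 with the GC trend removed). Lysosome and autophagy genes counted 12 higher and 4 lower of 24, with the same counts adjusted over the list alone and SQSTM1 at 0.88 (adjusted p = 0.0103, 0.458 with an estimated correlation and 0.0982 with the trend removed). HOX genes counted 12 lower and 1 higher of 27, with HOXD3 at -1.33, HOXB3 at -1.13 and HOXB13 at 0.92, yet as a list they did not stand apart from other genes (adjusted p = 0.419). Of the GIST lineage genes, 6 of 19 rose, among them the homeobox gene PITX1 (1.28), and 6 fell, among them KIT, PROM1 (-0.98) and BCHE (-2.31), with adjusted p = 0.708. Non-HOX targets of menin in leukaemia counted 8 lower and 1 higher of 13 (adjusted p = 0.276).

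In sgKMT2A libraries HOXD4 had the largest fall among called genes of at least 5 FPKM, from 14.3 ± 2.6 to 2.96 ± 0.8 FPKM (-1.96 ± 0.21, limma, n = 3 per group), and IGFBP3 (2.5 ± 0.11), VSTM2A (2.26 ± 0.17) and TAGLN (1.75 ± 0.20) rose, as in sgMEN1. FOS, an immediate-early transcription factor, went from 2.18 ± 0.46 to 15.2 ± 2.1 FPKM, and the matricellular gene CTGF rose by 2.03 ± 0.14. Falls also included the receptor gene PILRB (-1.88 ± 0.21), the small GTPase gene RASL11A (-1.66 ± 0.11), the chaperone regulator AHSA2 (-1.55 ± 0.23) and RHPN1 (-1.51 ± 0.17). Further falls were in the natriuretic peptide gene NPPC (-1.49 ± 0.39), MAPK8IP3 (-1.39 ± 0.21), the sterol exporter ABCG1 (-1.34 ± 0.10), STC2 (-1.28 ± 0.09) and B4GALNT4 (-1.23 ± 0.15). KIT did not pass (-0.10, adjusted p = 0.682). In all, 1502 genes passed (370 higher, 1132 lower), around a median of -0.0983 for all genes. Median centring gave 907, of which 484 were higher and 423 lower.

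HOX genes were lower as a list after sgKMT2A: 7 of 27 fell and 8 did so adjusted over the list alone, with HOXD3 at -1.23, HOXB3 at -0.89 and HOXB2 at -0.64. The list's camera adjusted p was 0.00765, against 0.122 with an estimated correlation, 0.135 with the GC and length trend removed and 0.0755 with a filter on a mean of at least 5 FPKM. Cholesterol genes fell (9 of 18, or 11 adjusted over the list alone; STARD4 -0.66, LSS -0.58; adjusted p = 0.000262, 0.0131 with an estimated correlation). Smooth-muscle contractile genes rose, 4 of 8 with 1 lower, or 5 and 1 adjusted over the list alone (ACTG2 1.71, ACTA2 1.05; adjusted p = 0.00044, 0.0131 with an estimated correlation). Interferon-stimulated genes rose in 4 of 17 and fell in 1, with IFIT1 at 0.84 (adjusted p = 0.000465, 0.0131 with an estimated correlation), and matrix genes rose in 7 of 17 and fell in 1, the same counts adjusted over the list alone, with POSTN at 1.25 (adjusted p = 4.55e-07, 0.136 with an estimated correlation). Fibroblast markers were higher in 2 of 7 and lower in 1, the same counts adjusted over the list alone (adjusted p = 0.00412, 0.0456 with an estimated correlation).

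Marker lists of RNA handling also moved with sgKMT2A. Replication-dependent histone genes, whose messages lack poly(A) tails, were higher in 9 of 14 members, or 12 adjusted over the list alone (HIST1H2BC 2.34, HIST1H2AC 1.87, HIST1H4H 1.70; camera adjusted p = 8.24e-15, 0.00033 with an estimated correlation). Immediate-early genes, which respond to handling as well as to signalling, were higher in 4 of 11, the same count adjusted over the list alone (FOS 2.35, JUN 1.32, EGR1 1.22; adjusted p = 3.55e-07, 0.0131 with an estimated correlation).

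The KAT6A and BRPF1 guides ask what needs the MOZ complex, in which BRPF1 holds the acetyltransferase KAT6A. Both lowered DUSP6, from 181 ± 3.6 to 103 ± 3.5 and 93.4 ± 1.2 FPKM, the prostaglandin synthase gene PTGS2 (-1.13 ± 0.13 and -0.92 ± 0.13), the heart and gut transcription factor gene HAND2 (-0.71 ± 0.09 and -0.61 ± 0.09), DHRS2 (-0.74 ± 0.10 and -0.71 ± 0.10) and IGDCC3 (-0.83 ± 0.08 and -0.47 ± 0.08). Both raised the matrix gene SMOC2 (1.18 ± 0.09 and 0.61 ± 0.09) and the stromal marker CD248 (0.72 ± 0.11 and 0.65 ± 0.11). With sgKAT6A the WNT genes APCDD1 (1.28 ± 0.15) and WNT11 (0.97 ± 0.10), LOXL4 (0.79 ± 0.11), CNTFR (0.77 ± 0.09), SOD3 (0.75 ± 0.12) and elastin, ELN (0.74 ± 0.09), rose, and SEMA7A (-0.69 ± 0.12), DUSP9 (-0.68 ± 0.12), HMGA2 (-0.67 ± 0.08) and SLC7A5 (-0.61 ± 0.08) fell. With sgBRPF1, DKK4 (0.72 ± 0.11), SEMA3E (0.58 ± 0.10), PPAP2B (0.50 ± 0.08) and SPARC (0.48 ± 0.08) rose and JUNB (-0.72 ± 0.11), GDNF (-0.50 ± 0.09) and ARMC9 (-0.40 ± 0.07) fell. By limma 84 genes passed for sgKAT6A (56 higher, 28 lower) and 18 for sgBRPF1 (8 higher, 10 lower), with 1132 and 692 at unadjusted p under 0.05. Median centring gave 52 and 10, and leaving out each library of the compared groups in turn took the counts to between 33 and 42 and between 2 and 7. KIT did not pass with either guide (-0.22, adjusted p = 0.695, and -0.12, adjusted p = 1).

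EGR1, an immediate-early gene downstream of ERK, parted these guides: it rose from 67.3 ± 1.9 to 147 ± 30 FPKM with sgKAT6A and fell to 18.6 ± 3.1 with sgBRPF1 (2.91 ± 0.15 between them). FOS (2.26 ± 0.19), JUNB (1.15 ± 0.11), IER2 (0.98 ± 0.15) and SMOC2 (0.57 ± 0.09) completed the 5 genes that passed in limma between sgKAT6A and sgBRPF1, all higher with sgKAT6A, with 371 at unadjusted p under 0.05. Immediate-early genes as a list were lower with sgBRPF1 (2 of 11, or 4 adjusted over the list alone; adjusted p = 1.72e-10, 0.00574 with an estimated correlation). Between the guides they differed with camera adjusted p = 1.1e-17, or 0.00107 with an estimated correlation. Such genes respond to handling as well as to signalling, and the cause of this difference was not tested. Markers of fibroblasts, which this line also expresses, were higher in 2 of 7 with sgKAT6A (DCN 0.68; 5 adjusted over the list alone) and in 0 of 7 with sgBRPF1 (3 adjusted over the list alone). Their adjusted p was 9.85e-08 (0.00502 with an estimated correlation) and 7.39e-07 (0.00574). Ribosome biogenesis genes under MYC had none past the threshold in either comparison, and as a list they were lower (adjusted p = 9.79e-06 and 6.28e-05, or 0.00502 and 0.00674 with an estimated correlation).

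Set against each other, sgMEN1 and sgKMT2A differed in 7255 genes (3175 higher, 4080 lower). With the GC and length trend removed, 2478 of 6815 called genes kept their calls and 648 turned to the opposite one. SEMA6B (1.44 ± 0.14), ZACN (1.43 ± 0.17) and the kinetochore gene SPC24 (1.30) were higher in sgMEN1, and EIF3E (-4.53), the nuclear noncoding RNA MALAT1 (-4.20 ± 0.29), SRP9 (-3.95 ± 0.16) and NDUFA5 (-3.95) lower, and these fold changes followed GC content with rho of 0.825. Their fold changes against sgLuc correlated across genes with r = 0.307, where unchanged groups simulated against the same controls gave 0.503, so part of this correlation comes from the shared controls. The covariance was 0.0721 against 0.0166 simulated. There were 268 genes higher with both, against 77.2 from independent lists, 619 lower with both against 452, and 54 opposite. For sgKAT6A and sgBRPF1 r was 0.664 (0.5 simulated; covariance 0.0232 against 0.0166), with 7 shared rises against 0.0382, 6 shared falls against 0.0239, and 1 opposite call. The 3 control libraries were not split, and part of the excess may come from them. The mean of sgMEN1 and sgKMT2A differed from the mean of sgKAT6A and sgBRPF1 in 6609 genes (1881 higher, 4728 lower; median of all genes -0.13), led by PILRB (-2.52 ± 0.15), HMGN5 (-2.32 ± 0.23) and the histone gene HIST1H4H (1.83 ± 0.35). This difference between means followed GC content with rho of 0.619. With the GC and length trend removed, 3893 of 6185 called genes kept their calls and 91 turned to the opposite one.

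**Figure D3:**
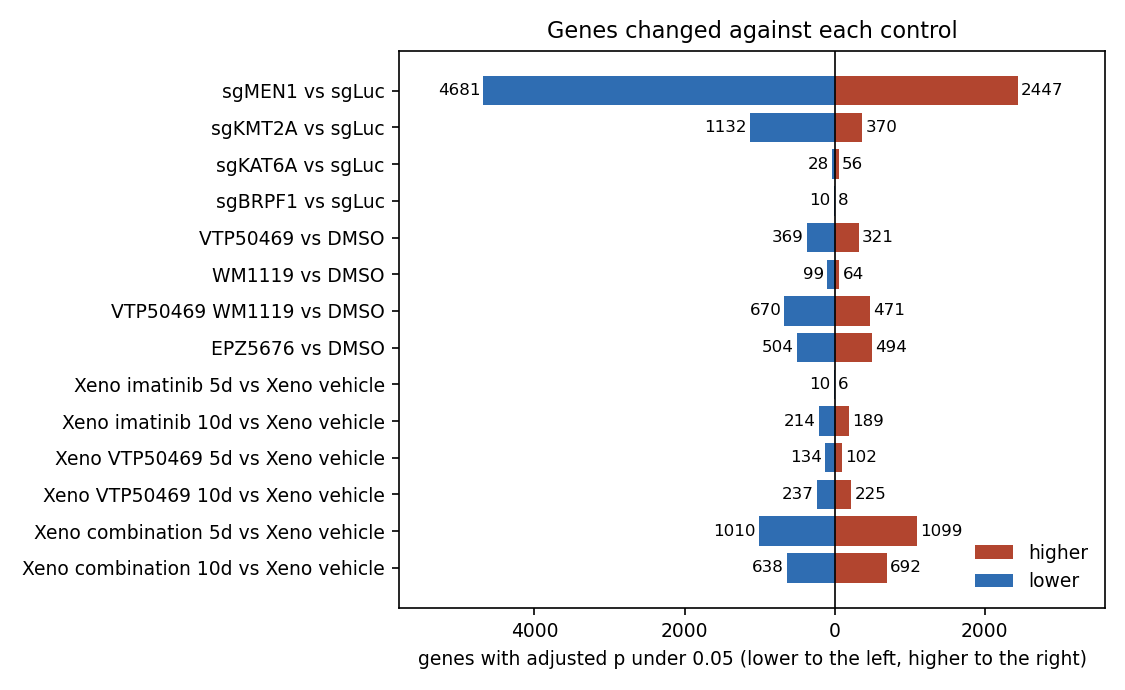
Genes past limma's adjusted threshold in the 14 comparisons with a control, as horizontal bars, higher genes to the right and lower genes to the left (number of genes), with 3 libraries per group for guides and 4 for drugs and xenografts. The bars run from 16 genes for 5 days of imatinib to 7128 for sgMEN1.

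VTP50469 in culture asks what blocking the menin pocket does to the same line. MMP1, an interstitial collagenase, fell from 44 ± 8.64 to 4.58 ± 1.81 FPKM (SD, n = 4; -3.05 ± 0.27) and GDF15, a stress cytokine, from 157 ± 22.1 to 22 ± 11 (-2.91 ± 0.28). KIT fell from 241 ± 9.94 to 155 ± 13.6 FPKM (-0.64 ± 0.11, limma adjusted p = 0.00153). LEMD1 (-1.71 ± 0.28), the noncoding RNA GAS5 (-1.52 ± 0.23), the polyamine enzyme gene SAT1 (-1.26 ± 0.17), the stress factors DDIT3 (-1.25 ± 0.18) and ATF3 (-1.16 ± 0.23), BCL3 (-1.24 ± 0.13), IGFBP7 (-1.23 ± 0.11) and MOXD1 (-1.20 ± 0.11) fell too. DKK4 rose from 77.1 ± 14.1 to 165 ± 38.5 FPKM, with the p53-induced gene TP53I3 (1.07 ± 0.20), the growth-arrest gene GADD45G (1.06 ± 0.20) and the chemokine gene CCL11 (1.05 ± 0.18). Also higher were FJX1 (0.98 ± 0.12), NSG1 (0.90 ± 0.18), the repressor gene HIC1 (0.90 ± 0.12), KIF26A (0.89 ± 0.17), CEND1 (1.13 ± 0.23) and the noncoding RNA DIRC3 (1.18 ± 0.14). KAT6B, the paralog of KAT6A, rose (0.51 ± 0.14, adjusted p = 0.0309). Across genes the fold changes followed GC content with rho of 0.379, and 523 of 645 called genes kept their calls with the GC and length trend removed. Of 12369 genes, 690 passed in limma (321 higher, 369 lower). Leaving out EPZ5676 replicate 3, which stood apart on the first principal component (63.5) and had 14074 genes above 0 against 14977 to 15279 in the others, raised the count to 1969, since all groups share the estimate of spread, while leaving out DMSO replicate 3 lowered it to 301.

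Of the 7 lists called with VTP50469, cholesterol genes alone kept the call with an estimated correlation. Unfolded-protein and ATF4 response genes fell in 4 of 18, or 9 adjusted over the list alone, with HERPUD1 at -0.54 and HSPA5 at -0.50 (camera adjusted p = 1.14e-06, 0.181 with an estimated correlation). Cholesterol genes fell in 3 of 18, or 11 adjusted over the list alone, with FDFT1 at -0.69 (adjusted p = 7.83e-06, 0.00625 with an estimated correlation). Glycolysis and hypoxia genes fell in 3 of 18, or 9 adjusted over the list alone, with EGLN3 at -0.85 (adjusted p = 9.91e-06, 0.102 with an estimated correlation). S-phase genes (1 of 26 higher; adjusted p = 9.11e-05, 0.255 with an estimated correlation) and MOZ complex genes (2 of 8 higher; 0.0255, 0.155) were called up. Respiratory chain genes (1 of 24 lower; 0.00572, 0.419) and housekeeping genes (2 of 14 lower; 0.0141, 0.244) were called down. Adjusted over the list alone these counts were 2, 3, 1 and 2. HOX genes did not move as a list (1 higher and 1 lower of 31, adjusted p = 0.846), nor did leukaemia targets of menin (0 of 13 by limma, adjusted p = 0.156).

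WM1119 left KIT (-0.07, limma adjusted p = 0.875), MMP1 (45.1 ± 10.2 FPKM against 44 ± 8.64 in DMSO) and GDF15 (133 ± 13.4 against 157 ± 22.1) without a call. DKK4 rose to 207 ± 19.8 FPKM (1.42 ± 0.16), as did the inflammatory caspase gene CASP1 (1.25 ± 0.19), GADD45G (1.22 ± 0.20) and the chondrogenic factor gene SOX6 (1.07 ± 0.10). So did LRRC17 (1.04 ± 0.16), the G-protein regulator RGS2 (1.04 ± 0.15), SERTAD4 (0.99 ± 0.14), the prostaglandin-degrading enzyme gene HPGD (0.91 ± 0.19) and IL17D (0.88 ± 0.14). Falls included IGFBP5 (-1.41 ± 0.11), the neuronal genes ASTN2 (-1.24 ± 0.19) and AMPH (-1.24 ± 0.13), the transcription factors MYB (-1.15 ± 0.13) and HAND2 (-1.03 ± 0.09). Others were the sodium pump subunit ATP1B2 (-1.12 ± 0.13), AIF1L (-1.06 ± 0.11), CHST1 (-1.02 ± 0.16), the phosphatase PTPRF (-0.99 ± 0.15), TRIM16 (-0.92 ± 0.12) and TLE2 (-0.91 ± 0.17). In all, 163 genes passed in limma (64 higher, 99 lower), against 87 without DMSO replicate 4, 499 without EPZ5676 replicate 3 and 1336 with library weights. Cholesterol genes fell as a list (1 of 18, or 7 adjusted over the list alone; adjusted p = 1.36e-07, 0.00131 with an estimated correlation). Leukaemia targets of menin counted MYB and MEIS2 (-0.73) lower of 13, with a median of 0.00479 although camera called them down (adjusted p = 0.0433, 0.423 with an estimated correlation).

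With both compounds DKK4 reached 328 ± 41.4 FPKM (2.09 ± 0.16) while GDF15 and MMP1 stood at 13.4 ± 5.88 and 4.27 ± 0.551. The ephrin receptor gene EPHA4 (1.87 ± 0.15), the neurotrophin gene NTF3 (1.60 ± 0.24), CCL11 (1.58 ± 0.18), the collectin gene COLEC10 (1.53 ± 0.19), SOX6 (1.43 ± 0.10), IGFBP3 (1.36 ± 0.18), the proteoglycan gene LUM (1.28 ± 0.17) and SEMA3E (1.17 ± 0.11) rose. ATP1B2 (-2.16 ± 0.13), ATF3 (-1.81 ± 0.23), CHST1 (-1.77 ± 0.16), CALCB (-1.75 ± 0.32), DDIT3 (-1.67 ± 0.18), BCL3 (-1.52 ± 0.13) and CEBPD (-1.49 ± 0.14) fell. KIT, at 194 ± 3.28 FPKM, did not pass (-0.31 ± 0.11, adjusted p = 0.0759). By limma 1141 genes passed (471 higher, 670 lower). ATF4 response genes fell in 10 of 18, or 15 adjusted over the list alone (ASNS -1.21, DDIT4 -1.17; adjusted p = 6.76e-11, 0.0355 with an estimated correlation). Cholesterol genes fell in 9 of 18 (DHCR7 -0.60; 0.00071 with an estimated correlation), glycolysis and hypoxia genes in 7 of 18 (VEGFA -1.0, BNIP3 -0.81; 0.0159), and direct p53 targets in 7 of 19 (BBC3 -0.97, TNFRSF10B -0.96, FAS -0.88; 0.0094). Adjusted over the list alone these counts were 11, 11 and 7. S-phase genes rose in 6 of 26, or 8 adjusted over the list alone (UHRF1 0.74, RRM2 0.68; adjusted p = 1.76e-06, 0.125 with an estimated correlation). Fibroblast markers rose in 3 of 7, the same count adjusted over the list alone (adjusted p = 0.00117, 0.0159 with an estimated correlation).

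Adding WM1119 to VTP50469 changed 459 genes (156 higher, 303 lower). These fold changes followed GC content with rho of -0.544, and 258 of 430 called genes kept their calls with the GC and length trend removed. The 459 included CASP1 (1.09 ± 0.19), the GTPase gene GBP3 (1.09 ± 0.18) and ASTN2 (-1.35 ± 0.19). Adding VTP50469 to WM1119 changed 657 (282 higher, 375 lower), among them the surface glycoprotein gene CD24 (1.58 ± 0.16), GDF15 (-3.31 ± 0.28) and MMP1 (-3.11 ± 0.27). VTP50469 and WM1119 differed in 1651 genes (906 higher, 745 lower), with FOXF2 (1.64 ± 0.16), BAI1 (1.62 ± 0.16) and AMPH (1.61 ± 0.13) higher with VTP50469 and CASP1 lower (-1.76 ± 0.19). This difference followed GC content with rho of 0.456, and 1089 of 1552 called genes kept their calls with the trend removed. Fold changes of VTP50469 and WM1119 against DMSO correlated across genes with r = 0.145, where unchanged groups gave 0.498 and DMSO libraries split between them gave -0.00265. The covariance of 0.00927 lay under the simulated 0.0164. Both raised 11 genes (1.66 from independent lists), lowered 14 (2.95) and moved 17 in opposite directions, a number that joins both opposite combinations. No expected number was computed for opposite calls in any pair, so these counts alone do not show agreement. No gene passed limma's interaction test of VTP50469 by WM1119 (0 genes, smallest adjusted p = 0.197, 837 at unadjusted p under 0.05).

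EPZ5676 asks whether blocking DOT1L, a methyltransferase that works with KMT2A fusion partners, acts on the same genes. It lowered MMP1 to 8.73 ± 4.62 and GDF15 to 38.6 ± 7.56 FPKM, KIT to 168 ± 30.4 (-0.53 ± 0.11, limma adjusted p = 0.0057; 0.124 on the compared groups only). It also lowered ATF3 (-1.32 ± 0.23), the asparagine synthetase gene ASNS (-1.31 ± 0.28), ATP1B2 (-1.29 ± 0.13), LEMD1 (-1.24 ± 0.28) and BCL3 (-1.14 ± 0.13). It raised DKK4 to 237 ± 37.1 FPKM, COLEC10 (1.76 ± 0.19), the TGF-beta family gene LEFTY1 (1.55 ± 0.27), CHST2 (1.38 ± 0.12), TP53I3 (1.35 ± 0.20), CD24 (1.27 ± 0.16), GADD45G (1.24 ± 0.20), NTF3 (1.16 ± 0.24) and the kinase gene ZAP70 (1.15 ± 0.20). Of 998 genes that passed, 494 were higher and 504 lower, and the count was 243 with library weights and 44 on the compared groups only, so most calls depend on the spread estimated with the other groups. Without EPZ5676 replicate 3, which stood apart (KIT 128 FPKM, rho with GC content of 0.762 against -0.354 to 0.233 in the others), 661 of the 998 kept their calls. With all libraries the fold changes followed GC content with rho of 0.463, and 833 of 934 called genes kept their calls with the GC and length trend removed. Cholesterol genes fell in 6 of 18 and rose in 0, or 11 and 1 adjusted over the list alone (HMGCS1 -0.71; adjusted p = 0.000156, 0.012 with an estimated correlation). Fibroblast markers rose in 3 of 7, or 6 adjusted over the list alone (LUM 0.78, FBLN1 0.64; adjusted p = 0.000143, 0.0115 with an estimated correlation). ATF4 response genes fell in 8 of 18, or 15 adjusted over the list alone (PSAT1 -0.84; adjusted p = 1.68e-07, 0.159 with an estimated correlation). Fold changes with EPZ5676 and VTP50469 correlated with r = 0.681 across genes (0.5 simulated, 0.511 with DMSO split; covariance 0.0585 against 0.0164). They shared 157 rises against 12.8 and 169 falls against 15 from independent lists, with 0 opposite calls.

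Guides and inhibitors of the same protein share no controls. Fold changes of sgMEN1 and VTP50469 correlated across genes with r = 0.351, with 165 shared rises (64.7 from independent lists), 206 shared falls (146) and 58 opposite calls, and r fell to 0.148 with the GC and length trend removed. KIT fell and DKK4 rose in both. For sgKAT6A and WM1119 r was 0.29, with 10 shared rises (0.269) and 10 shared falls (0.234), HAND2 and AIF1L among the falls. For sgBRPF1 and WM1119 r was 0.273, with 3 shared rises (0.0399) and 3 shared falls (0.0835). For sgKMT2A and VTP50469 r was 0.0855, with 28 shared rises (9.4), 55 shared falls (35.2) and 53 opposite calls.

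**Figure D4:**
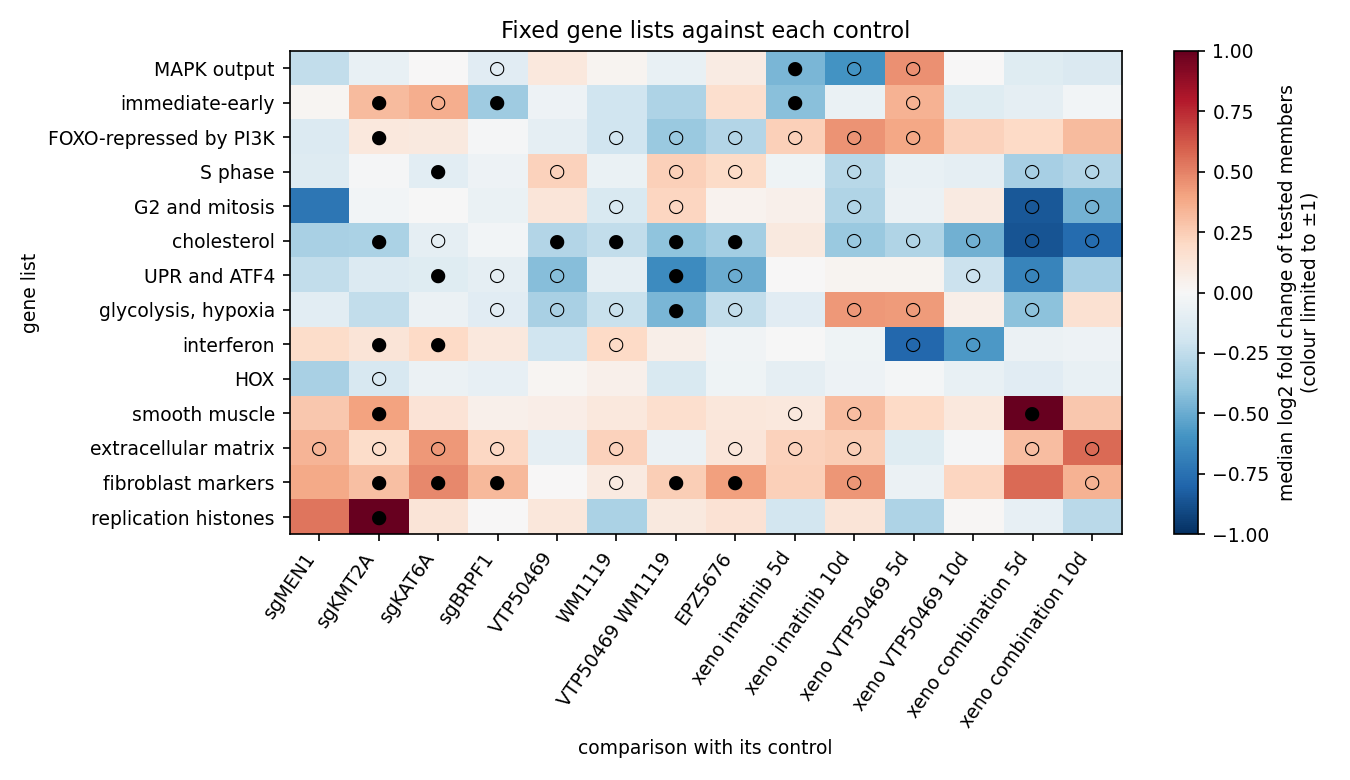
Median log2 fold change (colour, limited to 1 in either direction) of 14 fixed gene lists, one per line, in 14 comparisons with a control, one per column; an open dot marks a camera call with the preset correlation and a filled dot one that also held with an estimated correlation. Cholesterol genes were lower in all 4 drug columns.

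Imatinib in xenografts asks what loss of KIT signalling does to these tumors. After 5 days the ERK feedback genes DUSP6 and SPRY4 stood at 6.15 ± 1.17 and 20.6 ± 5.01 FPKM against 27.7 ± 5.82 and 86.5 ± 9.89 with vehicle (-2.0 ± 0.36 and -2.04 ± 0.36, limma, n = 4 per group). SPRY2 (-1.53 ± 0.20), the kinase gene NUAK1 (-1.51 ± 0.27), FAM212A (-1.18 ± 0.21), FGF23 (-1.0 ± 0.16), TRAF4 (-0.82 ± 0.16), ID1 (-0.66 ± 0.14), HOXD8 (-0.61 ± 0.11) and MAT2A (-0.59 ± 0.11) also fell. KLHL38 (1.87 ± 0.37), FAM181B (1.53 ± 0.29), the FOXO target CCNG2 (0.97 ± 0.19), PCDH18 (0.75 ± 0.14), the MYC antagonist MXD1 (0.71 ± 0.14) and CDC42EP3 (0.58 ± 0.11) rose. These were the 16 genes that passed of 12453, a count that fell to 1 without imatinib 5-day replicate 3 or vehicle replicate 1, and to at most 14 without any other library of these groups. ERK output genes fell as a list, 3 of 18 by the test of all genes and, adjusted over the list alone, 7 lower and 1 higher (adjusted p = 1.25e-10, 0.0278 with an estimated correlation). Immediate-early genes had 0 of 12 past limma's threshold and 4 lower adjusted over the list alone (adjusted p = 4.74e-05, 0.0292 with an estimated correlation). KIT itself, at 546 ± 41.2 against 455 ± 23.9 FPKM, did not pass (0.26, adjusted p = 0.775).

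After 10 days of imatinib DUSP6 (-2.15 ± 0.36), SPRY4 (-2.01 ± 0.36), FGF23 (-1.62 ± 0.16), the ETS factor ETV5 (-1.40 ± 0.31), SPRY2 (-1.39 ± 0.20), MYCN (-1.63 ± 0.27), RASL11A (-2.35 ± 0.48), the ribosome assembly gene RRS1 (-1.55 ± 0.29) and the tight-junction gene CLDN1 (-1.44 ± 0.30) were lower. FAM181B (2.13 ± 0.29), the FOXO-induced ubiquitin ligase gene FBXO32 (2.01 ± 0.35), CD24 (1.93 ± 0.29), the calcification inhibitor MGP (1.58 ± 0.33), MXRA8 (1.56 ± 0.26), FOXQ1 (1.26 ± 0.23), DTX4 (1.25 ± 0.18) and TBX20 (1.22 ± 0.29) were higher. In all, 403 genes passed (189 higher, 214 lower), but 2 did so on the compared groups only and 1047 with the libraries that stood apart left out. ERK output genes fell in 8 of 18 and rose in 1, or 9 and 2 adjusted over the list alone (adjusted p = 7.66e-07, 0.0976 with an estimated correlation). FOXO targets rose in 6 of 17, or 9 with 3 lower adjusted over the list alone (TXNIP 1.05, SESN3 1.02; adjusted p = 6.16e-05, 0.0976 with an estimated correlation). S-phase genes fell in 5 of 26, or 10 adjusted over the list alone (RRM2 -0.74, CDC6 -0.52; adjusted p = 4.88e-07, 0.245 with an estimated correlation). Sample names took 1 of 2 forms, one (form A) for all vehicle and 10-day VTP50469 libraries and imatinib 10-day replicates 1 and 2, the other (form B) for all remaining xenografts. DUSP6 stood at 2.19 and 2.87 FPKM in the form A libraries of 10-day imatinib and at 11.5 and 9.58 in the form B ones, with SPRY4 at 8.21 and 9.14 against 48.2 and 46.7. With form as a term 1321 genes passed. Form varies within no other group, so that term is estimated from these 4 libraries alone and carries their difference into each comparison of form A with form B.

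**Figure D5:**
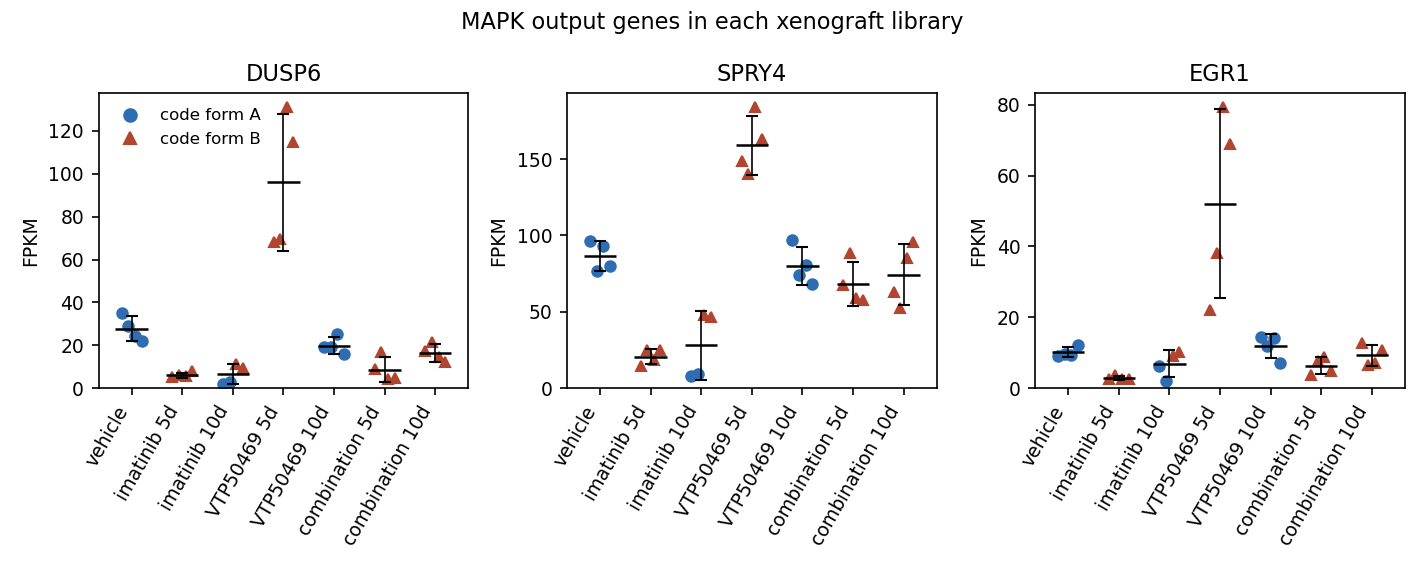
FPKM of DUSP6, SPRY4 and EGR1 in each of the 28 xenograft libraries by group (horizontal axis), with mean ± SD of 4; circles mark name form A and triangles form B. DUSP6 averaged 27.7 with vehicle, 6.15 after 5 days of imatinib and 96.1 after 5 days of VTP50469.

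VTP50469 in xenografts lowered the monooxygenase gene MOXD1 at 5 and 10 days (-1.65 ± 0.17 and -2.08 ± 0.17), FAM134B (-1.52 ± 0.23 and -1.57 ± 0.23) and the gap-junction gene GJB2 (-1.20 ± 0.24 and -2.05 ± 0.24). It raised FGF23 (1.49 ± 0.16 and 1.66 ± 0.16) and CD24 (1.24 ± 0.29 and 1.73 ± 0.29). Also higher were CCL11 (1.55 ± 0.34 and 1.60 ± 0.34), the adrenergic receptor gene ADRA2C (1.77 ± 0.34 and 1.47 ± 0.34) and SEMA6B (1.36 ± 0.19 and 1.47 ± 0.19). At 5 days the Notch target HES1 rose (1.80 ± 0.20) and MMP1 (-1.34 ± 0.28), the proteoglycan gene BGN (-1.32 ± 0.21), ALDH1A2 (-1.21 ± 0.17) and PLAGL1 (-1.07 ± 0.20) fell. At 10 days COLEC10 rose (1.5 ± 0.18) and the serotonin receptor gene HTR2B (-1.76 ± 0.21), HSPA4L (-1.41 ± 0.23), CLDN1 (-1.36 ± 0.30), HOXD1 (-1.24 ± 0.29), NETO2 (-1.19 ± 0.18) and B4GALT6 (-1.16 ± 0.15) fell. KIT stood at 321 ± 58 and 332 ± 42.5 FPKM against 455 ± 23.9 and did not pass (-0.52 ± 0.14, limma adjusted p = 0.0529; -0.46 ± 0.14, adjusted p = 0.0664). In limma 236 genes passed at 5 days (102 higher, 134 lower) and 462 at 10 days (225 higher, 237 lower). The 10-day count was lower without its replicate 4 and higher without the libraries that stood apart. Fold changes followed GC content with rho of 0.291 and 0.326. With the GC and length trend removed, 177 of 230 and 321 of 440 called genes kept their calls.

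The ERK genes DUSP6 and EGR1 stood at 96.1 ± 31.8 and 52.1 ± 26.5 FPKM after 5 days of VTP50469, against 27.7 ± 5.82 and 10.1 ± 1.45 with vehicle (1.72 ± 0.36 and 2.10 ± 0.36). At 10 days they were at 19.8 ± 3.94 and 11.9 ± 3.34, which gave 5 of the 7 genes that differed between the times, all lower at 10 days (DUSP6 -2.18 ± 0.36, EGR1 -1.92 ± 0.36, SPRY2 -1.44 ± 0.20, TRIB1 -1.24 ± 0.18, IER2 -1.17 ± 0.20). Replicates 3 and 4 of the 5-day group stood apart (13489 and 13153 genes above 0). Without them 58 genes passed at 5 days, 40 of them among the 236, and neither DUSP6 (1.31 ± 0.44, adjusted p = 0.204) nor EGR1 (1.45 ± 0.39, 0.104) did, although both values stayed positive in this fit with fewer libraries. Name form coincides with time for VTP50469. The form term, which takes the difference within 10-day imatinib off the 5-day values, left DUSP6 at 0.01 ± 0.48 (adjusted p = 0.994) and EGR1 at 0.88 ± 0.55 (0.337), and ERK output genes, called as a list at 5 days (4 of 18 higher; adjusted p = 0.000789, 0.245 with an estimated correlation), turned to the opposite direction (0.149). Interferon-stimulated genes were lower at 5 days, 1 of 23 with IFIT3 at -1.81 (without replicates 3 and 4, adjusted p = 0.348) and 17 adjusted over the list alone (adjusted p = 2.3e-10, 0.388 with an estimated correlation). Neuronal genes were higher at 10 days (3 of 6, the same count adjusted over the list alone; NEFL 1.08, SYP 0.78, NCAM1 0.67; adjusted p = 0.000437, 0.0198 with an estimated correlation).

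Against vehicle the combination of VTP50469 and imatinib changed 2109 genes at 5 days (1099 higher, 1010 lower) and 1330 at 10 days (692 higher, 638 lower). All its libraries had name form B and all vehicle libraries form A, so drug and form coincide. With form as a term, estimated within 10-day imatinib only, 831 and 560 of these genes kept their calls, which does not show whether form acts on the combination. The sterol and lipid genes SCD (-2.58 ± 0.32 and -1.93 ± 0.32), INSIG1 (-1.98 ± 0.27 at 5 days), SREBF2 (-1.71 ± 0.29) and DHCR7 (-1.58 ± 0.23) fell. LYPD6B (-1.86 ± 0.29 and -2.45 ± 0.29), the chromatin gene HMGA2 (-1.76 ± 0.19 and -1.97 ± 0.19), carbonic anhydrase CA2 (-1.66 ± 0.20 and -1.60 ± 0.20), HTR2B (-2.70 ± 0.21 at 10 days), MOXD1 (-1.82 ± 0.17) and MSRB3 (-1.48 ± 0.16) were lower too. The smooth-muscle actin gene ACTG2, listed at 0 in 2 of 4 vehicle libraries, reached 9.26 ± 1.65 and 6.91 ± 2.06 FPKM. CD24 (2.63 ± 0.29 and 2.57 ± 0.29), LEFTY2 (2.74 ± 0.35 and 1.72 ± 0.35), COL23A1 (2.21 ± 0.23 and 1.89 ± 0.23) and PSD (2.11 ± 0.29 and 2.13 ± 0.29) rose at both times. MXRA8 (2.45 ± 0.26) and ABI3BP (1.97 ± 0.25) were among the largest rises at 5 days. Those at 10 days included the GDNF receptor gene GFRA1 (2.35 ± 0.24), TMEM158 (1.91 ± 0.29), COLEC10 (1.89 ± 0.18) and the protease gene HTRA1 (1.83 ± 0.32). DUSP6 was lower at 5 days (-1.73 ± 0.36). KIT did not pass (0.02, limma adjusted p = 0.938; -0.17, adjusted p = 0.483).

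Cell-cycle and sterol genes were the lists that fell most with the combination, and their calls were lost with an estimated correlation. At 5 days 23 of 25 mitotic genes (25 adjusted over the list alone; PLK1 -1.30, AURKB -1.26, DLGAP5 -1.11) and 16 of 18 cholesterol genes (18 adjusted over the list alone; STARD4 -1.83) were lower, with camera adjusted p = 1.62e-17 and 4.04e-15, or 0.168 for each with an estimated correlation. S-phase genes fell in 11 of 26, or 13 adjusted over the list alone (RRM2 -1.44, CCNA2 -1.09; adjusted p = 2.09e-09, 0.239 with an estimated correlation). Smooth-muscle genes rose in 6 of 9 and fell in 1, or 7 and 1 adjusted over the list alone (TAGLN 1.65, TPM2 1.08; camera adjusted p = 0.00018, 0.0486 with an estimated correlation). Whether reads from mouse tissue add to rises with the combination was not tested. At 10 days 14 of 18 cholesterol genes (17 adjusted over the list alone; adjusted p = 2.51e-12, 0.291 with an estimated correlation) and 5 of 25 mitotic genes (11 adjusted over the list alone; KIF23 -0.86; adjusted p = 3.71e-08, 0.415 with an estimated correlation) were lower. NF-kB targets were higher in 4 of 9 at 10 days, the same count adjusted over the list alone (TNFAIP3 1.14, CXCL3 1.10, RELB 0.81; adjusted p = 0.000481, 0.0138 with an estimated correlation). Combination 10-day replicate 2 stood apart, with 12628 genes above 0 and an FPKM total of 752000.

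Against imatinib alone the combination changed 1672 genes at 5 days (817 higher, 855 lower) and 941 at 10 days (506 higher, 435 lower). The 10-day count was 51 on the compared groups only, and from 582 (without imatinib replicate 2) to 1060 (without imatinib replicate 4) with 1 library of these groups left out. ACTG2 (2.18 ± 0.29) and COL23A1 (1.98 ± 0.23) were higher at 5 days and SCD (-2.68 ± 0.32) and INSIG1 (-2.11 ± 0.27) lower. At 10 days FGF23 (2.36 ± 0.16), COLEC10 (1.97 ± 0.18) and ATRNL1 (1.89 ± 0.28) were higher and HTR2B (-1.93 ± 0.21), MOXD1 (-1.76 ± 0.17) and the receptor gene ERBB3 (-1.53 ± 0.23) lower. ERK output genes were higher than with imatinib alone at 10 days in 8 of 18, or 10 adjusted over the list alone (SPRY4 1.76, DUSP4 1.69, DUSP6 1.42; adjusted p = 4.25e-05, 0.107 with an estimated correlation). These values rest in part on the form A libraries of imatinib: with form as a term SPRY4 (0.60, adjusted p = 0.118) and DUSP6 (0.57, adjusted p = 0.376) lost their calls, DUSP4 (1.39) kept it and the list had an adjusted p of 0.0495. Against VTP50469 alone 1614 genes differed at 5 days (862 higher, 752 lower; LEFTY2 2.82 ± 0.35, MATN2 2.27 ± 0.22, DUSP6 -3.45 ± 0.36, HES1 -2.12 ± 0.20, SPRY2 -2.01 ± 0.20). At 10 days 149 differed (67 higher, 82 lower; TGM2 1.51 ± 0.24, LOXL4 1.19 ± 0.16, HMGA2 -1.01 ± 0.19, CXCL12 -1.01 ± 0.20). Drug and name form coincide in that comparison, and 18 of the 149 kept their calls with form as a term, these 4 named genes among them. The count was also far lower without VTP50469 replicate 1 and on the compared groups only. The limma interaction of the drugs called 89 genes at 5 days (44 higher, 45 lower). Leaving out 1 library of the groups involved gave 12 (combination replicate 3) to 155 (vehicle replicate 2). Of 100 splits of the libraries 5 reached 89, but such splits can carry the drugs' own effects, so chance was not excluded. The 89 included SCD (-2.27 ± 0.46), HES1 (-1.56 ± 0.28), CCNG2 (-1.48 ± 0.27), HSPB8 (-1.44 ± 0.21), SPON2 (2.23 ± 0.46) and MATN2 (1.84 ± 0.31). At 10 days it called 4: C12orf5 (1.27 ± 0.22), ERBB3 (-1.75 ± 0.32), DTX4 (-1.44 ± 0.26) and TUFT1 (-1.33 ± 0.25). None of the 4 kept its call with form as a term (adjusted p from 0.458 to 0.517).

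Between 5 and 10 days 1 gene differed with imatinib, METRNL (1.00 ± 0.17), with 1216 at unadjusted p under 0.05, and 32 with the combination (14 higher and 18 lower at 10 days), among them COLEC10 (1.14), the chaperone gene HSPB8 (0.85), STRA6 (-0.99) and BCAM (-0.94). The METRNL call was lost with a replicate block and without a filter, and 3 of 35 splits gave as many genes. The calls of the combination were lost on the compared groups only. At 10 days the combination's fold changes correlated across genes with those of VTP50469 (r = 0.665; 0.502 simulated from shared vehicle libraries, 0.436 with them split; covariance 0.0813 against 0.0252), with 166 shared rises (12.5 from independent lists) and 153 shared falls (12.1). With imatinib r was 0.497 (0.5 simulated, 0.291 split; covariance 0.0604 against 0.0252), with 71 shared rises (10.5), 55 shared falls (11) and 4 opposite calls. VTP50469 in culture and in xenografts shared no controls: r was 0.234 at 5 days (38 shared rises against 2.63, 40 shared falls against 3.96) and 0.334 at 10 days (63 against 5.37, 55 against 7.04), with CCL11 among the shared rises and MOXD1 among the shared falls.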

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

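The tests of the sgMEN1 excess and of a stronger loss of ERK output were chosen only after the results they explain were seen, as were the settings that remove the GC and length trend or leave out the libraries that stood apart.

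Several genes of the KIT pathway and of drug response had 1 library far from the other 3 of its group. KIT stood at 226 FPKM in DMSO replicate 1 (244 to 247 in the others) and GDF15 at 27.4 in EPZ5676 replicate 1 (41.5 to 43.7). EGR1 stood at 3.79 in imatinib 5-day replicate 2 (2.49 to 2.67) and at 12.3 in vehicle replicate 4 (9.18 to 9.6), and ACTG2 at 2.11 in VTP50469 5-day replicate 4 (0.212 to 0.456). Among totals, genes above 0 numbered 15183 in DMSO replicate 4 (14915 to 14948) and 12628 in combination 10-day replicate 2 (14396 to 14565), and FPKM summed to 752000 in the latter (530300 to 536100). VTP50469 replicate 2 summed to 533400 (605200 to 615600), with 8.52% in its 10 highest genes (10.7 to 10.8%), and imatinib 10-day replicate 1 had 10.3% there (7.74 to 8.08%). These are 11 of 91 checks, each of 1 measure in 1 group, past Dixon's limit of 0.829, where chance passes about 1 in 20. The checks are not independent, since a library can pass in several. Some genes were also chosen after their values were seen, so the share is not a test of excess.

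Between 10 and 5 days, limma's test of the difference called 1 gene with imatinib, METRNL (1.00), 7 with VTP50469 and 32 with the combination. With VTP50469 they included the ERK and immediate-early genes DUSP6 (-2.18), EGR1 (-1.92), SPRY2 (-1.44), TRIB1 (-1.24) and IER2 (-1.17). With the combination COLEC10 (1.14), CCDC3 (0.95), HSPB8 (0.85) and MRPL52 (0.84) were higher at 10 days and BRICD5 (-2.0), STRA6 (-0.99), BCAM (-0.94), ACSF2 (-0.91) and FAM65C (-0.88) lower. Without the libraries that stood apart, none of these 5 genes of VTP50469 kept its call (adjusted p from 0.0918 to 0.267) in a fit with fewer libraries, although all stayed negative (DUSP6 -1.77, EGR1 -1.26, SPRY2 -1.26, TRIB1 -0.94, IER2 -0.76), and time coincides with name form there.

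KIT, DUSP6 and HOXD4 fell and IGFBP3 and DKK4 rose with sgMEN1, within a response of 7128 genes against 1502, 84 and 18 with the other guides. After removal of a smooth trend with GC content and length of the reference transcripts, 3565 of 6691 genes kept call and direction. KIT (-0.81) and HOXD4 (-2.75) were among them. These values argue against such a trend as the whole source. GC or length bias that it does not capture was not tested and stays possible. Lower depth is argued against by relative depths of up to 0.906 in sgMEN1, above the lowest other library (0.678). A GC trend as a part of it is in line with rho of 0.734 across genes, with 498 genes turned to the opposite call. An effect of MEN1 loss shared with KMT2A loss may add to it: with the trend removed the covariance of their fold changes was 0.0776 (r = 0.535), against 0.0118 simulated from the shared controls and at most 0.0135, and what gave the libraries their trend stays open.

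In the xenografts DUSP6 and EGR1 rose after 5 days of VTP50469 in a group whose replicates 3 and 4, like combination 10-day replicate 2, stood apart, with DUSP6 at 131 and 115 FPKM there against 68.3 and 69.8. Reads from mouse tissue were not seen as a rise of 14 marker genes of other cells (median of -0.0869). The lists used include fibroblast markers, which this line expresses itself, so this does not exclude such reads. Fewer reads cannot be told apart from other sources. Over 28 libraries relative depth and genes above 0 had rho of 0.427 (permutation p = 0.025), between the bounds set. Their r was 0.5 (permutation p = 0.00634, and 0.491 without the 2 farthest). This relation covers all xenografts, and the depth of combination 10-day replicate 2 had no clear peak. VTP50469 5-day replicates 3 and 4 had relative depths of 0.76 and 0.807. Combination 5-day replicate 4, at 0.647, had 14616 genes above 0, and vehicle replicate 2, at 0.764, had 13723. RNA degradation cannot be told apart either, since deviations from group mates followed transcript length with rho of -0.38, -0.297 and -0.367. Slower loss of ERK output in some animals was not tested. It would not lift levels above vehicle, yet DUSP6 lay at 68.3 to 131 FPKM against 22.2 to 35.3 with vehicle. EGR1 lay at 22.2 to 79.3 against 9.18 to 12.3. For these genes the values argue against slower loss as the source of the rise, although name form differs between the groups.

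DUSP6 and SPRY4 were lower in the form A than in the form B libraries of 10-day imatinib. A batch marked by the name form cannot be told apart from other sources. That difference was compared across genes with the one between VTP50469 at 10 days (form A) and 5 days (form B). The correlation was -0.0246 (0.0832 without the libraries that stood apart), so no difference shared over all genes was seen. Time goes with form in the VTP50469 groups, however. DUSP6 was lower in form A there too (19.8 ± 3.94 against 96.1 ± 31.8 FPKM), as was SPRY4 (79.9 ± 12.6 against 159 ± 19). A stronger loss of ERK output in the form A animals cannot be told apart from other sources: the median difference of 18 ERK output genes was -0.568 within imatinib, but -0.268 between the VTP50469 groups, or -0.182 without the libraries that stood apart, and time differs there too. The number of libraries, 2 against 2, keeps this open.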

How the results depend on the processing

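Settings chosen only after the data were seen were those that left out libraries that stood apart, used one name form only, or removed the GC and length trend. The cause was not tested for any result below unless stated. Over all settings without a library left out, 2 named genes lost their sgMEN1 call and took the opposite sign, ANO1 with median centring (0.0126, adjusted p = 0.923) and ETV1 with the GC and length trend removed (0.0449, adjusted p = 0.716). KIT, HOXD4, DUSP6, IGFBP3 and DKK4 kept their sgMEN1 calls. Of 524 gene results, those that lost a call numbered 20 with a pseudocount of 0.1, 41 without a filter, 0 of the 435 tested with a mean of at least 5 FPKM, 15 with median centring (besides ANO1), 12 with quantile normalization, 15 with a replicate block and 15 with library weights. They numbered 103 on the compared groups only, 43 of 229 with name form as a term, 27 without the libraries that stood apart (fewer libraries), 6 of 43 with one name form and 15 of 511 with the GC and length trend removed (besides ETV1). ETV1 with VTP50469 gained a call in 4 settings: library weights, the compared groups only, without the libraries that stood apart, and the GC and length trend removed. Leaving out each library of the compared groups in turn ended a call in 573 of these tests and kept the result in 3497, in fits with fewer libraries.

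Of 236 list calls, 32 held with an estimated correlation. With name form as a term, xenograft list calls numbered fewer than the 137 without it, and 6 turned to the opposite direction. These were ERK output after 5 days of VTP50469 (adjusted p = 0.149), ERK output (0.0377), ATF4 response (0.655) and neuronal genes (0.889) between the times of VTP50469, and interferon (0.134) and antigen-presentation genes (0.533) in the combination against VTP50469 at 10 days.

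Scaling moved the smaller guide counts: median centring gave 907 for sgKMT2A, 52 for sgKAT6A and 10 for sgBRPF1. Quantile normalization gave 29 for sgBRPF1, 27 for imatinib at 5 days, 98 between the times of the combination and 161 for the 5-day interaction of VTP50469 with imatinib. A replicate block, although numbers do not pair samples, gave 10 for sgBRPF1 and 0 by limma between the times of imatinib. Without a filter limma called 0 genes between the times of imatinib, 40 for the 5-day interaction and 0 for the 10-day one.

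Library weights gave 3937 for sgKMT2A, 681 for sgKAT6A, 320 for sgBRPF1 and 24 between the latter. They gave 3479 for VTP50469, 1336 for WM1119, 3190 for both, 243 for EPZ5676, 2389 for both against VTP50469, 2241 against WM1119, 4423 for VTP50469 against WM1119 and 108 for their interaction. For these cultures the estimation of the weights stopped before it converged. In xenografts they gave 236 and 263 for imatinib at 5 and 10 days, 569 and 1275 for VTP50469, and 3728 and 2260 for the combination. They gave 4059 for it against imatinib at 5 days, 2799 and 728 against VTP50469, 70 and 218 between the times of VTP50469 and of the combination, and 1161 for the 5-day interaction.

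Without the libraries that stood apart sgKMT2A gave 2578, sgKAT6A 269, sgBRPF1 67 and the latter against each other 8. All 84 genes of sgKAT6A were among the 269. VTP50469 gave 1969 (all 690 among them), WM1119 499, both 2291, both against VTP50469 1661 and against WM1119 1483, VTP50469 against WM1119 3195 and the interaction 2. In xenografts imatinib gave 50 and 1047, VTP50469 58 and 939, the combination against imatinib at 5 days 2577 and against VTP50469 at 10 days 430, imatinib between times 6, VTP50469 between times 0 by limma, and the interactions 251 and 22.

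With the GC and length trend removed sgKMT2A gave 2396, sgKAT6A 299, sgBRPF1 77 and the latter against each other 8, VTP50469 1053, WM1119 481, both 2086, EPZ5676 1644, both against WM1119 1433 and the interaction 2. Imatinib at 5 days gave 32, its times 0 by limma, the times of the combination 56 and the interactions 192 and 2. Correlations across genes became 0.535 for sgMEN1 and sgKMT2A, 0.187 for sgMEN1 and sgKAT6A and 0.148 for sgMEN1 and VTP50469.

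On the compared groups only, where the spread comes from those libraries alone, sgBRPF1 gave 10, VTP50469 2616, WM1119 374, both 2319, EPZ5676 44, both against VTP50469 1728 and against WM1119 1005, VTP50469 against WM1119 3116 and the interaction 1. Imatinib gave 78 and 2, VTP50469 at 5 days 56, the combination at 10 days 559, against imatinib 3361 and 51, against VTP50469 at 10 days 22, the times of VTP50469 2, those of the combination 0 by limma, and the interactions 384 and 0.

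With name form as a term, which is estimated from the 10-day imatinib libraries alone, imatinib gave 474 and 1321, VTP50469 at 5 days 1117, the combination against imatinib at 10 days 426, the times of imatinib 0 by limma, of VTP50469 236 and of the combination 73, and the interactions 699 and 0. With one name form imatinib at 10 days gave 1338, the combination against it 480 and the times of imatinib 0 by limma.

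Libraries of other groups also move counts, through the shared estimate of spread, and are not in the ranges that follow. Leaving out each library of the compared groups in turn gave, from the lowest count to the highest, 822 (without sgLuc replicate 2) to 1155 for sgKMT2A, 33 (sgKAT6A replicate 2) to 42 for sgKAT6A, 2 (sgBRPF1 replicate 1) to 7 for sgBRPF1 and 3 in every case between them. For VTP50469 it gave 301 (DMSO replicate 3) to 520, for WM1119 87 (DMSO replicate 4) to 171, for both 718 (their replicate 4) to 970, and for EPZ5676 456 (DMSO replicate 2) to 2183 (EPZ5676 replicate 4). Both gave 199 (VTP50469 replicate 1) to 408 against VTP50469 and 262 (their replicate 4) to 641 against WM1119, and VTP50469 against WM1119 1025 (VTP50469 replicate 2) to 1314.

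In xenografts imatinib gave 1 (its replicate 3 or vehicle replicate 1) to 14 at 5 days and 84 (its replicate 1) to 705 (its replicate 3) at 10 days, and VTP50469 71 (its replicate 4) to 353 and 238 (its replicate 4) to 385. The combination gave 1285 (its replicate 3) to 1827 and 804 (vehicle replicate 4) to 1271. It gave 1057 (its replicate 3) to 1383 and 582 (imatinib replicate 2) to 1060 against imatinib, and 875 (its replicate 3) to 1691 and 27 (VTP50469 replicate 1) to 208 against VTP50469. Between times the counts were 0 to 2 for imatinib by limma, 3 to 7 for VTP50469 and 6 (combination 5-day replicate 2) to 148 (10-day replicate 3) for the combination. The interactions gave 12 (combination replicate 3) to 155 (vehicle replicate 2) and 0 (VTP50469 replicate 1) to 75 (imatinib replicate 4). FPKM gives no read counts, so what depth limits could not be measured beyond the relative depths.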

Other observations

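All genes named in these first paragraphs were chosen after their values were seen, and the test of dependence on KMT2A was chosen before its result. ETV1, an ETS factor that cooperates with KIT in this tumor type, fell from 39.7 ± 2.4 to 21.1 ± 1.2 FPKM (SD, n = 3) with sgMEN1 (-0.88 ± 0.08, limma adjusted p = 5.42e-07) and did not pass with sgKMT2A (-0.08, adjusted p = 0.528). Its fall was absent once the GC and length trend was removed (0.04, adjusted p = 0.716). The channel gene ANO1 fell less with sgMEN1 (-0.35 ± 0.09), and median centring left 0.01 (adjusted p = 0.923). With VTP50469 in culture ETV1 had a value of 0.39 ± 0.15 that did not pass (adjusted p = 0.139) but passed in 4 other settings, such as without EPZ5676 replicate 3 (adjusted p = 0.00047). In xenografts the combination raised it by 0.46 ± 0.12 at 5 and 0.44 ± 0.12 at 10 days. HOXD4, lower with both sgMEN1 and sgKMT2A, stood at 53.6 ± 7.5 FPKM with VTP50469 against 48 ± 2.5 with DMSO (0.15 ± 0.17, adjusted p = 0.653). HAND2, lower with sgKAT6A, sgBRPF1, sgKMT2A and WM1119, stood at 37.1 ± 0.58 FPKM with sgMEN1 against 37.3 ± 2.9 in sgLuc. The difference between guide and inhibitor was not tested.

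CD24 rose with menin inhibition and with imatinib in xenografts: 4.75 ± 0.69 FPKM with vehicle, 18.8 ± 6.7 after 10 days of VTP50469, 23.1 ± 14 after 10 days of imatinib and 33.3 ± 6.3 with both. COLEC10 rose with VTP50469 at 10 days (12.9 ± 1.4 against 3.93 ± 0.77 FPKM) and with the combination (17.7 ± 4.8), and did not pass with imatinib (-0.08, adjusted p = 0.872). In culture COLEC10 went from 3.34 ± 0.24 to 13.9 ± 3.4 FPKM with EPZ5676. Lists of the menin-MLL complex, the DOT1L partners, the GIST lineage and epithelial markers were called by camera in 0 of 30 comparisons, BCL2-family genes in 1 and Polycomb subunits in 2. The menin-MLL complex counted 3 of 9 members lower and 1 higher with sgMEN1, MEN1 among the lower.

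MMP1, GDF15 and KIT were among the genes lower with both VTP50469 and EPZ5676. A hypothesis was that such genes depend on KMT2A. Of 168 genes lower with both drugs, 31 (18.5%) were lower with sgKMT2A, against 1099 of 11454 others (9.59%), an odds ratio of 2.13 (1.39 to 3.19, two-sided Fisher's exact test, p = 0.000517). Genes are not independent replicates, and the sgKMT2A libraries share no controls with the drugs. Expression level, which can make a gene easier to call in both experiments, was not accounted for. Some of these genes may depend on KMT2A, but the odds ratio does not separate that from ease of calling. Most, KIT among them, were not called with sgKMT2A. Over all genes sgKMT2A and VTP50469 had r of 0.0855, with 28 shared rises, 55 shared falls and 53 opposite calls.

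Other splits of the same libraries were counted for each number of genes. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real counts were 7128 for sgMEN1, 1502 for sgKMT2A, 84 for sgKAT6A and 18 for sgBRPF1, with a highest other of 0 for each, 7255 between sgMEN1 and sgKMT2A (highest other 0) and 5 between sgKAT6A and sgBRPF1 (highest other 2). For the means of the guides 1 of 100 drawn splits gave as many as 6609, the real one, and the highest other gave 4823. The GC and length trend was not removed in these splits, so they do not separate it from an effect of the guides.

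In culture 1 of 35 splits, the real one, reached the count of each drug. Chance is argued against at that share only, if libraries are separate samples. It is the smallest share that 35 splits allow and is not adjusted over comparisons. The counts were 690 for VTP50469 (highest other 0), 163 for WM1119 (1), 1141 for both (1), 998 for EPZ5676 (6), 459 and 657 for both against VTP50469 (1) and WM1119 (0) and 1651 between these (0). In xenografts the same held for imatinib at 5 days (16, highest other 1) and 10 days (403, 39), VTP50469 (236, 112; 462, 3) and the combination (2109, 1; 1330, 253). It held too for the combination against imatinib (1672, 1; 941, 296) and against VTP50469 (1614, 1; 149, 2), and the times of VTP50469 (7, 3) and of the combination (32, 1). Chance was not excluded for the times of imatinib, where 3 of 35 splits gave at least 1 gene (highest other 2), nor for the interactions with imatinib, where 5 of 100 splits reached 89 (highest other 440) and 8 of 100 reached 4 (highest other 392). The drawn splits move libraries between all groups of an interaction, so the drugs' own effects can enter it. These splits therefore cannot tell chance from such effects. The real split also follows name form for the combination and for 5 days of imatinib or VTP50469 against vehicle, for 10 days of the combination against VTP50469 and for the times of VTP50469. The culture interaction had 0 genes by limma (837 at unadjusted p under 0.05), a count that 100 of 100 splits must reach (highest other 13), so its splits say nothing about chance.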
